A study of Homo sapiens with 6 samples.

How the data were processed

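The series holds messenger RNA sequencing of DAOY cells 48 h after transfection with 50 nM of a small interfering RNA (siRNA) against SMO (siSMO) or of a negative control siRNA (siNC), with 3 samples in each of 2 groups. Groups were taken from the sample labels. The labels do not say how far the numbered replicates were independent cultures, and the siRNA sequences, and whether each siRNA was 1 sequence or a pool, are not given in the sources used here.

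The deposited gene table gives whole-number read counts per gene and sample for 37163 genes, per the file headers. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.3, HTSeq 0.6.0, DESeq2 1.6.3 and the genome build hg38 without giving each a role, and the annotation release and the use of strand in counting are not given in the sources used here. Deposited FPKM values (fragments scaled to transcript length and library size) were made by the authors from the same samples, per the file headers. The deposited gene table also gives, per the file headers, a signal column with the authors' mean normalized count, a fold ratio, a log2 fold change of siSMO over siNC, and p-values unadjusted and adjusted, whose model is not stated. Deposited enrichment tables give p-values, q-values or FDR of gene ontology terms and KEGG maps, by a tool that is not stated. All of these deposited values served for description only, except the counts, and the FPKM values, which served in the naming rule and in an alternative.

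Total counts were 17279317, 17865686 and 17599544 in siNC 1 to 3 and 17739639, 16779339 and 17141376 in siSMO 1 to 3. On average 17541 ± 51.7 genes in siNC and 17576 ± 132 genes in siSMO (SD, n = 3) had at least 10 counts. The 10 most abundant genes held 6.13% ± 0.192 and 6.33% ± 0.0410 of counts, and protein-coding genes held 97.96% and 97.84%. No row of the table failed to name a gene, and 76 symbols were held by more than 1 gene ID, which were kept apart by ID.

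Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (17560 genes kept), TMM scaling (factors 0.992 to 1.01), a robust quasi-likelihood fit with the group as the only term, and the quasi-likelihood F test. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors and 95% intervals of log2 fold changes come from this fit. CPM are counts scaled to the TMM-scaled library size with edgeR's cpm. Gene lists (34 lists, 822 entries, of which 790 matched the table) were tested with camera of limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry. The test, the lists, the naming rule and the alternatives, except those named below as added, were chosen before the data were examined.

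The text names SMO and 6 other Hedgehog genes (PTCH1, GLI1, GLI2, GLI3, SUFU and HHIP). It names the 12 largest rises and 12 largest falls among protein-coding genes past the threshold, with a mean FPKM of at least 1 in the higher group and no overlap between groups. It also names up to 4 members of each list past the threshold with the smallest p, or 2 members as values where none passed. Some genes that this rule selects are not reported here. Genes named as overlapping or as pseudogene copies, and the genes of a KEGG map, were added after their values were seen.

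The procedure was tested on simulated counts of 17253 genes with 50 genes changed at each fold. It recovered 42%, 72%, 84% and 100% of those changed 1.2-, 1.5-, 2- and 3-fold (21, 36, 42 and 50 genes). It also called 15 of 17058 unchanged genes. The simulation changed 200 genes, against 5999 called in the data, so these shares need not hold there.

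After the data were seen, sequences shared by the changed genes were sought. Each 7-base sequence (7-mer) was scored by the regression of log2 fold change, limited to ±1.5, on its presence in the 3' untranslated region (3' UTR), after removal of the trend with log length, its square and base composition. This used 12318 protein-coding genes with a 3' UTR of at least 50 bases and a mean of at least 2 CPM (GENCODE release 29, transcript with the longest 3' UTR), 7-mers in at least 50 genes, and 100 permutations of the log2 fold changes. Coding sequences of 12271 genes were scanned likewise. In simulated data the scan recovered 20, 20 and 14 of 20 planted 7-mers at effects of -0.4, -0.2 and -0.1. These were falls planted in 3' UTRs on 7-mers within a limited range of gene numbers. Rises, coding sequences and more common 7-mers were not simulated. Sequences and plots were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

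Alternatives were each sample left out in turn, the replicate number as a block, no filter, a stricter filter (at least 5 CPM in 3 samples), DESeq2 size factors or library size in place of TMM, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) with a mean FPKM of at least 0.5, and other thresholds. Added after seeing the data were leaving out genes that carry the 7-mers of the fallen genes and offsets for GC content and length. Counts within 1.5 times the reported count were taken as the same, and direction was compared only where a call was made. The labels' protocol speaks of paired preparations but states no paired model. After removal of group means, same-numbered samples correlated at 0.054, 0.069 and 0.107 over 8835 genes, not all above the limit of 0.1 set for pairing, so the reported fit has no block. Each of these lay above the pairs of different number (-0.085 to 0.033), so pairing is not excluded, and the block served as an alternative.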

Results

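Messenger RNA was sequenced from DAOY cells, a human medulloblastoma line that the labels place in the Sonic Hedgehog subtype. The cells had received 50 nM of small interfering RNA (siRNA) against SMO or 50 nM of a negative control siRNA, and RNA was taken 48 h later. Whether each was 1 sequence or a pool is not given in the sources used here. SMO is the membrane protein that passes the Hedgehog signal on once its inhibitor PTCH1 is bound by ligand. The 2 groups, siNC (control) and siSMO, held 3 samples each. Total counts per sample ran from 16779339 to 17865686, and between 17425 and 17671 genes had at least 10 counts in a sample. Pairs of replicates differed by more than counting noise, with a mean chi-square per gene of 1.88 to 2.87, as repeat libraries of 1 culture would also do. The labels number the replicates and speak of 3 cases of paired siNC and siSMO cells without saying how far the cultures were independent, so p-values measure the spread between these samples, which may be partly technical. The comparison asks which transcripts changed when SMO was silenced.

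SMO mRNA fell in all 3 siSMO samples, which places each sample where its label does. The gene (ENSG00000128602, GRCh38/hg38 chromosome 7, positions 129188872 to 129213545, plus strand) had 71.0 ± 2.45 normalised counts (CPM; SD, n = 3) in siNC and 18.2 ± 1.62 CPM (SD, n = 3) in siSMO, so that 25.7% of the control level was left. The counts behind these values were 1170 to 1294 per siNC sample and 277 to 350 per siSMO sample. The log2 fold change was -1.96 with a standard error (SE) of 0.064 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.5e-29). The 2-sided exact permutation test of the 3 against 3 values gave p = 0.1, the smallest that this design allows.

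PTCH1, the Hedgehog receptor and itself a transcriptional target of the pathway, fell to 62.7% of its control level, from 53.3 ± 2.76 to 33.4 ± 0.804 CPM (SD, n = 3). SUFU, which restrains the GLI transcription factors, fell 1.30-fold from 23.1 ± 1.34 to 17.8 ± 0.229 CPM, and GLI3 fell 1.15-fold from 105 ± 3.03 to 91.2 ± 2.84 CPM (SD, n = 3). Their log2 fold changes with SE were -0.67 ± 0.059, -0.38 ± 0.081 and -0.20 ± 0.043 for PTCH1, SUFU and GLI3, with edgeR adjusted p = 2.5e-13, 0.00022 and 0.00014. GLI2 was 43.9 ± 0.518 CPM in siNC and 39.6 ± 0.977 CPM in siSMO (SD, n = 3), a log2 fold change of -0.15 ± 0.058 (SE) with edgeR adjusted p = 0.040. The GLI2 call ended when siNC 1, siNC 2, siSMO 1, siSMO 2 or siSMO 3 was left out, with edgeR adjusted p = 0.095, 0.096, 0.14, 0.056 and 0.067, and under 4 other settings with adjusted p between 0.069 and 0.12 (0.034 to 0.14 over all 13 alternatives). GLI1 and HHIP did not pass the threshold. GLI1, the transcription factor most directly induced by Hedgehog signalling, was at 1.19 ± 0.019 CPM in siNC and 1.08 ± 0.322 CPM in siSMO (SD, n = 3), with a 95% confidence interval of the log2 fold change from -0.78 to 0.51 (edgeR adjusted p = 0.79). HHIP, a decoy receptor for the ligand, was at 5.95 ± 0.239 and 6.60 ± 0.377 CPM (edgeR adjusted p = 0.44). Its siSMO values lay above its siNC values (exact permutation p = 0.1), and its log2 fold change ran from 0.057 to 0.18 over 13 alternatives. Groups did not overlap for 44.0% of all genes tested. GLI1 overlaps ARHGAP9 and HHIP overlaps HHIP-AS1, GLI2 carries in its coding sequence a 7-base sequence described below, and whether the counting used strand is not given in the sources used here.

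**Figure D1:**
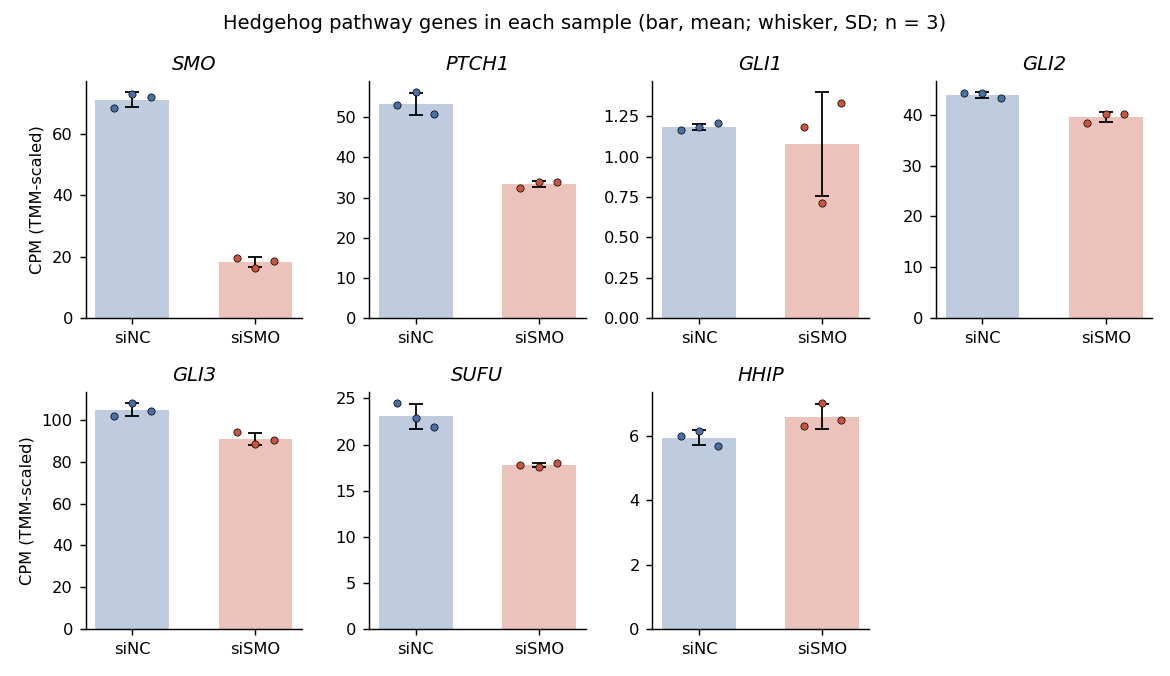
Normalised read counts (CPM, vertical axis, each from 0) of 7 Hedgehog pathway genes in the siNC and siSMO samples. Bars show the mean of 3 samples, whiskers the SD and points the single samples. SMO and PTCH1 were lower in each siSMO sample than in any siNC sample, and the GLI1 values of the groups overlapped.

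Across the transcriptome, 5999 of 17560 genes tested changed, 2899 of them higher and 3100 lower in siSMO (edgeR, adjusted p under 0.05). Most changes were small. The median absolute log2 fold change of the changed genes was 0.33, 1258 of them changed by at least 1.5-fold and 363 by at least 2-fold. Of these 363 genes, 152 were higher and 211 lower. The 3 values of each group did not overlap for 5692 of the 5999 changed genes and for 7726 of all genes tested (44.0%, where chance gives 10%). The first principal component of 8835 genes held 83.6% of the variance and separated the groups, while the second held 5.83%. The common biological coefficient of variation was 3.59%, so that replicates lay close together.

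**Figure D2:**
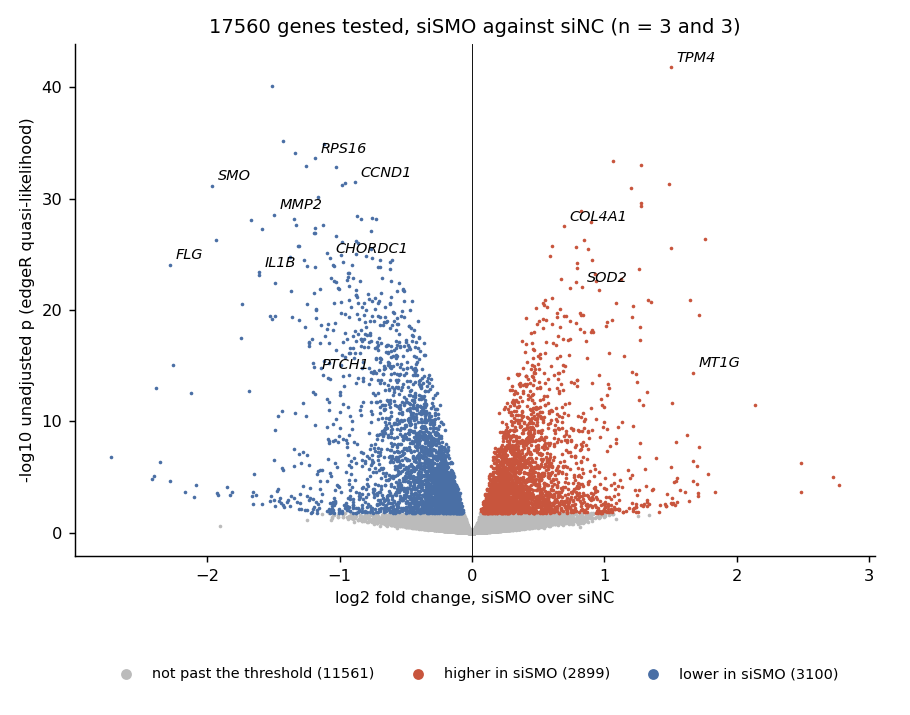
Log2 fold change of siSMO over siNC (horizontal axis) against -log10 of the unadjusted edgeR p (vertical axis) for 17560 genes, n = 3 and 3. Red points mark the 2899 genes higher and blue points the 3100 genes lower in siSMO, and grey points those not past the threshold. TPM4 had the smallest p, and SMO and FLG lie among the points furthest from 0 with a small p.

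Among protein-coding genes, FLG, the precursor of the skin barrier protein filaggrin, fell furthest under the rule for named genes, 4.84-fold from 23.9 ± 1.40 to 4.92 ± 0.671 CPM (SD, n = 3). It was followed by PLAC8 (4.78-fold), SMO (3.89-fold), B4GAT1, a glycosyltransferase that acts on dystroglycan (3.81-fold), the chemokine gene CCL26 (3.79-fold), NPPB, which encodes a natriuretic peptide (3.59-fold), the transcription factor KLF2 (3.36-fold), the nucleoporin NUP35 (3.33-fold), CDK15 (3.21-fold), the mitochondrial ribosomal protein MRPL34 (3.17-fold), VIPR1, a receptor for vasoactive intestinal peptide (3.04-fold), and the inflammatory cytokine IL1B (3.04-fold). Their log2 fold changes ran from -2.28 for FLG (SE 0.109) to -1.60 for IL1B (SE 0.080). The order depends on the scale, since with limma-trend on log2(FPKM + 1) the log2 fold change was -1.04 for FLG, -1.07 for PLAC8, -0.76 for CCL26, -0.84 for NPPB and -0.72 for CDK15, against -1.73 for SMO. The sequence CTACCGA or TACCGAA, the pair of 7-base sequences that went furthest with lower levels, was found in the 3' untranslated region (3' UTR) of B4GAT1, NUP35 and MRPL34 and in the coding sequence of SMO and KLF2. FLG held only their shared 6 bases, TACCGA. Other named genes with only these 6 bases are given under other observations. FLG overlaps FLG-AS1, MRPL34 overlaps ABHD8 and VIPR1 overlaps VIPR1-AS1, and KLF2 has pseudogene copies, so the values of these genes are uncertain to that extent.

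The metallothionein genes MT1M (3.29-fold) and MT1G (3.18-fold), whose products bind zinc and other metals, the homeobox gene MEOX1 (3.28-fold), the lymphotoxin gene LTB (3.17-fold) and RGS16, a regulator of G protein signalling (3.14-fold), were among the protein-coding genes that rose furthest under the rule for named genes. CGB8 rose 3.08-fold, RAET1L 2.91-fold, the zinc finger gene ZNF681 2.85-fold, TPM4, a tropomyosin of the actin cytoskeleton, 2.83-fold and OGFR 2.83-fold. TPM4 was the most abundant of them, at 396 ± 8.18 CPM in siNC and 1123 ± 24.0 CPM in siSMO (SD, n = 3). With limma-trend on log2(FPKM + 1) the log2 fold change was smaller for MT1M (1.13 against 1.72), LTB (0.84 against 1.66), RAET1L (0.70 against 1.54) and ZNF681 (0.68 against 1.51). CGB8, RAET1L, MT1M and MT1G belong to families of closely similar genes between which reads can be split.

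Of 34 gene lists fixed before the data were examined, 5 passed the threshold in a test of each list against all other genes (camera with a preset correlation of 0.01, Benjamini-Hochberg over the lists). With a correlation estimated from these samples none of the 5 passed. Under fry, which asks whether a list moves one way without comparing it to other genes, 14 lists passed, the 5 and the lists of Hedgehog components, G1/S, G2/M, p53, heat shock, NOTCH, YAP/TAZ, EMT and small RNA machinery. Median, mean and camera direction differed in sign for 13 lists, none of them past the threshold: apoptosis, NF-kB, cholesterol, fatty acids, glycolysis, hypoxia, stress response, TGF-beta, oxidative phosphorylation, histones, progenitors, neurons and muscle. Below, values after gene names are log2 fold changes ± SE from 3 against 3 samples, and adjusted p-values of lists are those of camera. For each of the 5 lists the lowest adjusted p over the alternatives came with no filter, which adds low-count genes to those compared against. It need not mean a larger change: the median of the Hedgehog targets was -0.118 there, against -0.117 as reported. For 22 of the 34 lists the counts of changed members adjusted over the list alone equalled those over all genes tested, and for the others both are given.

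The Hedgehog target genes fell as a list. Of 22 tested members, 7 fell and none rose, with a median log2 fold change of -0.12 (camera adjusted p = 0.00097; adjusted p = 0.58 with an estimated correlation, the highest over 17 alternatives, whose lowest was 5.3e-08). Without siSMO 3 the median was -0.19. The members with the smallest p were CCND1, which encodes the G1 cyclin D1 (-0.88 ± 0.028, from 943 ± 10.7 to 512 ± 18.2 CPM, SD, n = 3), the Polycomb gene BMI1 (-0.73 ± 0.063), PTCH1 and the transcription factor SOX9 (-0.51 ± 0.045). None of these 4 carried either 7-base sequence in its 3' UTR or coding sequence. Of 22 Hedgehog pathway components, 3 rose and 7 fell (camera adjusted p = 0.14). They included SMO, PTCH1 and GRK2, a kinase that phosphorylates SMO (-0.46 ± 0.052), while GPR161, a ciliary receptor that restrains the pathway, rose (0.35 ± 0.054). With no filter on low counts and under fry this list passed, with adjusted p = 0.0082 and 0.0042 (up to 0.68 over 17 alternatives). The list holds SMO, the siRNA target itself, and was not tested without it, so these calls are no independent sign of a pathway response. WNT target genes fell, with 6 of 15 lower and none higher (7 lower adjusted over the list alone), a median of -0.25 and camera adjusted p = 0.021 (adjusted p = 0.58 with an estimated correlation, the highest over 17 alternatives, whose lowest was 0.0015). They were led by CCND1, which stands in both lists, by DKK1, a secreted WNT inhibitor (-0.48 ± 0.104), by the receptor FZD7 (-0.34 ± 0.078) and by WISP1 (-0.83 ± 0.213). The WNT call ended without siNC 3 (median -0.14, adjusted p = 0.074), without siSMO 1 (-0.18, adjusted p = 0.12) and under the stricter filter (-0.21, adjusted p = 0.062).

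**Figure D3:**
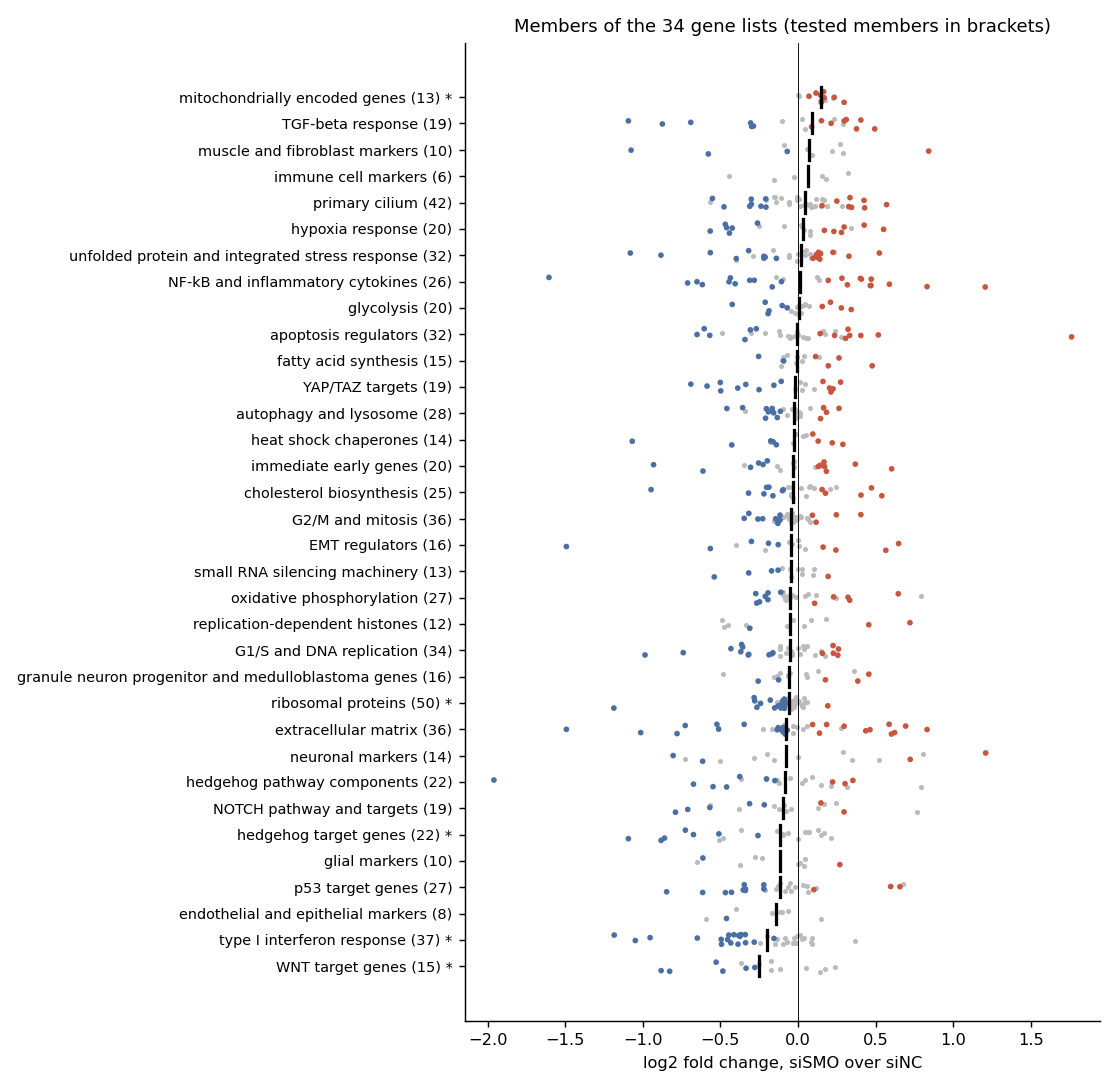
Log2 fold change of siSMO over siNC (horizontal axis) of each tested member of the 34 gene lists (vertical axis, number of tested members in brackets). Red and blue points are members higher and lower in siSMO past the threshold, grey points the others, and black bars the medians. The 5 lists marked with an asterisk passed camera with a preset correlation, and none of them passed with an estimated one.

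The type I interferon response list fell, with 18 of 37 members lower and none higher (19 lower adjusted over the list alone), a median of -0.20 and camera adjusted p = 0.00097 (adjusted p = 0.66 with an estimated correlation, the highest over 17 alternatives, whose lowest was 5.3e-08). With limma-trend on FPKM the median was -0.12. Its members with the smallest p were the transcription factor IRF1 (-0.45 ± 0.049), DDX58, which encodes the RNA sensor RIG-I (-0.39 ± 0.045), OAS1, which senses double-stranded RNA (-1.18 ± 0.145), and SAMD9L (-0.50 ± 0.061). NF-kB and inflammatory cytokine genes went both ways, with 11 of 26 higher and 11 lower (12 and 11 adjusted over the list alone; camera adjusted p = 0.76). ICAM1, an adhesion molecule (-0.71 ± 0.035), IL1B (-1.60 ± 0.080) and TNFAIP2 (-0.62 ± 0.036) fell, while SOD2, the mitochondrial superoxide dismutase, rose (0.83 ± 0.031, from 776 ± 46.5 to 1380 ± 5.98 CPM, SD, n = 3). Of 20 immediate early genes 7 rose and 6 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.48). PHLDA1 (-0.61 ± 0.032), the growth factor signalling inhibitor SPRY4 (-0.93 ± 0.059) and the ERK phosphatase DUSP6 (-0.31 ± 0.041) fell, and IER3 rose (0.18 ± 0.031). TNFAIP2 and SPRY4 carried one of the 7-base sequences in the 3' UTR, IRF1 overlaps C5orf56, and SOD2 overlaps ACAT2 and WTAP.

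Neither list of cell cycle genes passed camera. In the G1/S and DNA replication list 5 of 34 members rose and 11 fell (camera adjusted p = 0.14), among them the phosphatase CDC25A (-0.99 ± 0.058), the polymerase alpha subunit POLA1 (-0.74 ± 0.064), FEN1 (-0.37 ± 0.037) and the helicase subunit MCM5 (-0.32 ± 0.040). In the G2/M and mitosis list 4 of 36 rose and 9 fell (camera adjusted p = 0.48). AURKA (-0.35 ± 0.039), the kinesin KIF23 (-0.32 ± 0.041) and the transcription factor FOXM1 (-0.26 ± 0.036) fell, whereas BIRC5, which encodes survivin, rose (0.40 ± 0.036). Of 27 p53 target genes 3 rose and 10 fell (camera adjusted p = 0.27). TP53INP1 (-0.85 ± 0.094), the cell cycle inhibitor CDKN1A (-0.47 ± 0.043), the stress cytokine GDF15 (-0.61 ± 0.083) and ZMAT3 (-0.35 ± 0.064) were among those that fell. Of 32 apoptosis regulators 8 rose and 6 fell (camera adjusted p = 0.69), with BIRC5 higher and the inhibitor BIRC3 (-0.65 ± 0.050) and the pore-forming BAK1 (-0.60 ± 0.057) lower. With no filter on low counts the G1/S and p53 lists passed, with adjusted p = 0.0046 and 0.022 (up to 0.68 and 0.87 over 17 alternatives). CDC25A carried one of the 7-base sequences in the 3' UTR, and POLA1, FEN1, KIF23 and BIRC3 in the coding sequence. FEN1 overlaps FADS2, FOXM1 overlaps ITFG2 and RHNO1, TP53INP1 overlaps NDUFAF6 and POLA1 overlaps the pseudogene EEF1B2P3.

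Of 13 transcripts of the mitochondrial genome tested, 9 rose and none fell, with a median log2 fold change of 0.15 (camera adjusted p = 0.012; adjusted p = 0.75 with an estimated correlation, the highest over 17 alternatives, whose lowest was 3.1e-05). MT-ND2 rose by 0.30 ± 0.031, MT-ND1 by 0.23 ± 0.029, MT-CO2 by 0.17 ± 0.026 and MT-CO3, which overlaps MT-ATP6, by 0.16 ± 0.025. The mitochondrial share of all counts was 3.58% ± 0.141 in siNC and 3.96% ± 0.0441 in siSMO (SD, n = 3). Nuclear genes of oxidative phosphorylation did not move as a list, with 5 of 27 higher and 7 lower (camera adjusted p = 0.92). Cytochrome c, CYCS (0.32 ± 0.036), rose, and UQCRC1 (-0.25 ± 0.035) and ATP5A1 (-0.21 ± 0.034) fell. Ribosomal protein genes fell as a list by a median of -0.06, with 20 of 50 lower and 1 higher (camera adjusted p = 0.012; adjusted p = 0.89 with an estimated correlation, the highest over 17 alternatives, whose lowest was 1.4e-05). RPS16 stood apart at -1.19 ± 0.031, from 721 ± 27.7 to 317 ± 11.3 CPM (SD, n = 3), and RPL4 (-0.27 ± 0.026), RPL31 (-0.28 ± 0.032) and RPS20 (-0.28 ± 0.034) fell less. The ribosomal protein call ended without siSMO 1 (median -0.048, adjusted p = 0.073), under the stricter filter (-0.056, adjusted p = 0.066) and without the genes that carry one of the 7-base sequences in the 3' UTR (-0.056, adjusted p = 0.10). It held without the genes that carry one in the 3' UTR or coding sequence (-0.064, adjusted p = 0.019). RPS16, RPL31 and ATP5A1 carried one in the 3' UTR. ATP5A1 also overlaps HAUS1, RPL31 overlaps TBC1D8, and ribosomal protein genes have many pseudogene copies.

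In lipid metabolism, 5 of 25 cholesterol biosynthesis genes rose and 8 fell (camera adjusted p = 0.92). INSIG1, a sterol-sensing regulator (0.54 ± 0.032), rose, while the enzymes NSDHL (-0.95 ± 0.067) and LSS (-0.22 ± 0.035) fell. Of 15 fatty acid synthesis genes 4 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.63), with ME1 (0.48 ± 0.040), the desaturase FADS2 (0.26 ± 0.033) and SREBF1 (0.19 ± 0.032) higher and the desaturase SCD (-0.25 ± 0.028) lower. Of 20 glycolysis genes 4 rose and 6 fell (camera adjusted p = 0.92). The glucose transporter SLC2A1 (-0.42 ± 0.031) and LDHA (-0.19 ± 0.028) fell, and PFKL (0.34 ± 0.040) and PFKFB3 (0.28 ± 0.048) rose. Of 20 hypoxia response genes 6 rose and 6 fell (camera adjusted p = 0.72), those that fell including the growth factor VEGFA (-0.57 ± 0.034), SLC2A1, SLC2A3 (-0.44 ± 0.047) and NDRG1 (-0.47 ± 0.057). SLC2A3 and LSS carried one of the 7-base sequences in the coding sequence. FADS2 overlaps FADS1 and FEN1, and SREBF1 overlaps RAI1.

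Of 32 genes of the unfolded protein and integrated stress response 10 rose and 9 fell (camera adjusted p = 0.77). VLDLR (-0.88 ± 0.068), the serine metabolism enzyme SHMT2 (-0.40 ± 0.036), the transcription factor ATF4 (-0.32 ± 0.030) and its target CHAC1 (-1.08 ± 0.113) fell. Heat shock chaperones split, with 4 of 14 higher and 5 lower (camera adjusted p = 0.48). The HSP90 co-chaperone CHORDC1 (-1.07 ± 0.050) and BAG3 (-0.43 ± 0.046) fell, and HSPD1 (0.29 ± 0.028) and HSPB1 (0.22 ± 0.037) rose. Of 28 autophagy and lysosome genes 4 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.69), with GABARAPL1 (-0.36 ± 0.055) and WIPI1 (-0.46 ± 0.087) lower and ULK1 (0.26 ± 0.046) and CTSL (0.18 ± 0.041) higher. Of 12 replication-dependent histone genes HIST1H2BD (0.72 ± 0.102) and HIST1H4H (0.46 ± 0.117) rose and HIST1H2AC (-0.31 ± 0.077) fell (camera adjusted p = 0.92), and the last lost its call with limma-trend on FPKM (adjusted p from 0.00017 to 0.062 over 13 alternatives). In the small RNA silencing machinery 1 of 13 genes rose and 4 fell (camera adjusted p = 0.48). AGO1, an Argonaute protein (-0.54 ± 0.047), the precursor exporter XPO5 (-0.32 ± 0.038) and DICER1 (-0.17 ± 0.038) fell and DROSHA rose (0.19 ± 0.046). The DICER1 call ended with limma-trend on FPKM (adjusted p from 9.4e-05 to 0.052 over 13 alternatives). AGO1 and XPO5 carried one of the 7-base sequences in the coding sequence, WIPI1 overlaps ARSG, and XPO5 overlaps POLR1C.

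Of 36 extracellular matrix genes 11 rose and 14 fell (11 and 15 adjusted over the list alone; camera adjusted p = 0.47). The gelatinase gene MMP2 fell 2.81-fold, from 690 ± 22.7 to 245 ± 14.6 CPM, and SPARC, a collagen-binding glycoprotein, fell 1.66-fold, from 693 ± 3.81 to 418 ± 5.93 CPM (SD, n = 3). The collagen genes COL4A1 (0.69 ± 0.028) and COL5A1 (0.60 ± 0.026) rose. Of 16 regulators of the epithelial-mesenchymal transition (EMT) 4 rose and 5 fell (camera adjusted p = 0.29), with the cadherin CDH2 (0.57 ± 0.034) and VIM (0.16 ± 0.027) higher and MMP2 and the repressor ZEB2 (-0.57 ± 0.052) lower. In the TGF-beta response list 8 of 19 rose and 6 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.92). TGFBI rose (0.40 ± 0.025), while the feedback inhibitors PMEPA1 (-0.87 ± 0.040) and SKI (-0.69 ± 0.044) and the ligand BMP4 (-1.09 ± 0.112) fell. Of 19 YAP/TAZ targets 5 rose and 9 fell (camera adjusted p = 0.12), among them TEAD1 (-0.69 ± 0.034), the receptor tyrosine kinase AXL (-0.50 ± 0.036), ANKRD1 (-0.50 ± 0.051) and FJX1 (-0.59 ± 0.073). The YAP/TAZ list passed without siNC 3 (adjusted p = 0.048), and it and the EMT list passed with no filter (0.0054 and 0.015, where the highest over 17 alternatives were 0.68 and 0.96). Of 19 NOTCH pathway genes 2 rose and 5 fell (camera adjusted p = 0.46). The receptor NOTCH2 (-0.31 ± 0.028), its modifier LFNG (-0.71 ± 0.070) and the ligand DLL1 (-0.57 ± 0.096) fell and the coactivator MAML2 rose (0.30 ± 0.064). MMP2, ZEB2, PMEPA1 and AXL carried one of the 7-base sequences in the 3' UTR and TEAD1 in the coding sequence. COL4A1 overlaps COL4A2 and DLL1 overlaps FAM120B.

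Of 42 genes of the primary cilium, the organelle in which SMO acts, 8 rose and 8 fell (9 and 10 adjusted over the list alone; camera adjusted p = 0.80). CEP164 (0.42 ± 0.058) and IFT27 (0.57 ± 0.081) rose and EFCAB7 (-0.55 ± 0.099) and the motor subunit KIF3A (-0.30 ± 0.064) fell. CEP164 overlaps BACE1, and EFCAB7 overlaps ITGB3BP and carried one of the 7-base sequences in the coding sequence. Among 16 genes of granule neuron progenitors and medulloblastoma 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.77), with SOX4 (0.46 ± 0.038), PDLIM3 (0.38 ± 0.094) and YAP1 (0.18 ± 0.044) higher. ZIC2 was lower (-0.26 ± 0.082), a call that ended without siNC 1 (log2 fold change -0.16) or siSMO 3, with DESeq2 and with limma-trend on FPKM (adjusted p from 0.00065 to 0.18 over 13 alternatives).

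Markers of other cell types did not move as lists. Of 14 neuronal markers 2 rose and 2 fell (camera adjusted p = 0.97). GAD1 (0.72 ± 0.112) and ELAVL4 (1.21 ± 0.237) rose and NEFL (-0.61 ± 0.049), with one of the 7-base sequences in its 3' UTR, fell. GRIN1 was lower (-0.80 ± 0.312), a call that ended without siNC 1, siNC 3, siSMO 1 or siSMO 2 and with no filter (adjusted p from 0.032 to 0.14 over 10 alternatives). Of 10 glial markers MBP was lower (-0.61 ± 0.209) and SLC1A3 higher (0.27 ± 0.102), neither past the threshold adjusted over the list alone (camera adjusted p = 0.92). The MBP call ended without siNC 1, siNC 2, siSMO 2 or siSMO 3 and with DESeq2 (adjusted p from 0.0016 to 0.12 over 11 alternatives). The SLC1A3 call ended without siNC 2, siNC 3, siSMO 1 or siSMO 2, with no filter, with DESeq2 and with limma-trend on FPKM (adjusted p from 0.016 to 0.16 over 13 alternatives), and SLC1A3 carried one of the 7-base sequences in its 3' UTR. None of the 6 immune cell markers tested passed (camera adjusted p = 0.97). CD74 was at 1.97 ± 0.302 and 1.44 ± 0.868 CPM and CD14 at 1.52 ± 0.637 and 1.91 ± 0.207 CPM in siNC and siSMO (SD, n = 3), and CD74 passed without siSMO 1 (adjusted p from 0.046 to 0.93 over 12 alternatives). Of 8 endothelial and epithelial markers PECAM1 was lower (-0.46 ± 0.158; camera adjusted p = 0.90), a call that ended without siNC 3, siSMO 1 or siSMO 2, with DESeq2 and with limma-trend on FPKM (adjusted p from 0.0063 to 0.23 over 13 alternatives). Of 10 muscle and fibroblast markers 1 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.76). PDGFRB (-1.08 ± 0.083) and S100A4 (-0.58 ± 0.101), which overlaps S100A3, fell, and CNN1 rose (0.84 ± 0.237), a call that ended with limma-trend on FPKM (adjusted p from 0.00042 to 0.053 over 12 alternatives). COL1A1, at 4786 ± 188 and 4559 ± 75.6 CPM (SD, n = 3), differed by -0.07 ± 0.025, a call that ended without siNC 3 (log2 fold change -0.039), siSMO 1 or siSMO 2, under scaling by library size and with limma-trend on FPKM (adjusted p from 0.014 to 0.28 over 13 alternatives).

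The authors' deposited table marked 216 genes as changed, 79 higher and 137 lower, all with an absolute log2 fold change of at least 1 and an adjusted p under 0.05. All 216 were tested here, on the same counts, and 215 passed the edgeR threshold in the same direction. That threshold sets no fold change. With both of the authors' limits the edgeR fit called 363 genes, 214 of them among the authors' 216. The authors' deposited table gave SMO a log2 fold change of -1.96 and PTCH1 -0.67. It held 14827 genes with an adjusted p, 4426 of them under 0.05, the same numbers as DESeq2 without a block gave here. The DESeq2 alternative is therefore no independent check of the authors' values. The authors' deposited enrichment tables listed 405 biological process terms and 22 molecular function terms with a false discovery rate under 0.05, and no cellular component term or KEGG map. Glycosaminoglycan biosynthesis led the process terms in the authors' deposited table, with 9 of the called genes among 137, 3 higher and 6 lower. In the authors' deposited table the KEGG map of Hedgehog signalling in the fly held 4 called genes, FBXW11, BMP4, SMO and GRK6, all lower, with q = 0.12. SMO, the siRNA target, and GRK6 carried one of the 7-base sequences in the coding sequence, and FBXW11 held only the shared bases TACCGA.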

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

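The alternatives that leave out carriers of the 7-base sequences and those with GC content and length offsets were chosen after seeing the data. SMO was lower and past the threshold in each of 14 alternatives, with a log2 fold change from -2.02 to -1.89 leaving out 1 sample and of -1.73 with limma-trend on FPKM. No result past the threshold reversed. Of 149 genes besides SMO under the naming rule, 144 were past the threshold, and 134 of these stayed past it in every alternative that gave a value. The 7 others that depended on a sample are named in the report with the samples, and 3 more (HIST1H2AC, DICER1 and CNN1) lost the call with limma-trend on FPKM only.

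The number of changed genes went from 5999 to between 4992 and 5717 leaving out 1 sample (2357 to 2720 higher, 2635 to 2997 lower), where fewer samples were tested. It was 5612 with no filter, 5513 of 11802 under the stricter filter, 5995 with DESeq2 size factors, 6021 by library size (53.4% of them higher, against 48.3%), 4426 with DESeq2 (4400 of them shared), 4398 with limma-trend on FPKM (4158 shared) and 4408 at an adjusted p under 0.01. With the replicate number as a block it was 6225, of which 5985 were shared. With at least a 2-fold change required it was 363, 152 higher and 211 lower. It was 5318 without carriers in 3' UTR or coding sequence, 5784 without carriers in the 3' UTR, and 5840 against 5715 of 14067 genes with the offsets (5145 shared). Of the authors' 216 genes, 215 passed as reported, 213 to 215 leaving out 1 sample, 182 with limma-trend on FPKM and 148 under the stricter filter, where fewer genes were tested, and between 214 and 216 in the other alternatives run for them.

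The number of lists depended more on the setting. It went from 5 to 10 with no filter, 3 under the stricter filter, 0 with an estimated correlation, 14 with fry and 3 to 5 leaving out 1 sample (3 without siSMO 1). It was 5 without carriers in 3' UTR or coding sequence and 4 without carriers in the 3' UTR, where the median of the ribosomal proteins was -0.056 against -0.060 as reported, so the call ended with little change in size. The median of the Hedgehog components, SMO among them, was -0.13 with no filter (adjusted p = 0.0082) and -0.086 with fry (adjusted p = 0.0042), past the threshold in both, and ran from -0.10 to -0.033 leaving out 1 sample. The median of the Hedgehog targets was -0.12 with an estimated correlation (adjusted p = 0.58), no longer past the threshold, and ran from -0.19 (without siSMO 3) to -0.12 leaving out 1 sample. It was smaller, though past the threshold, under the stricter filter (-0.076) and with limma-trend on FPKM (-0.072). With limma-trend on FPKM the medians of the interferon and WNT lists were also smaller (-0.12 against -0.20 and -0.15 against -0.25), and so, by over 1.5 times, were the changes of OAS1 (-0.63), WISP1 (-0.32), GAD1 (0.40), PECAM1 (-0.18), CNN1 (0.38) and 9 of the largest rises and falls, given in the report. Adjusted p over 17 alternatives ran from 0.0042 to 0.68 for the components and from 5.3e-08 (with no filter) to 0.58 for the targets. The cause was not tested, beyond fry posing another question and the estimated correlation resting on few samples. Alternatives planned for a series with FPKM only did not apply. Depth limits GLI1, under 2 CPM.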

Other observations

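All tests in this part were chosen only after the result was seen, except the scans for 7-base sequences in 3' UTRs and the test of GC content and length, whose predictions were written before they were run, with the pattern widened afterwards to changes of 2-fold or more.

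Families of genes that share the start of their name, 309 with at least 7 tested genes, were searched after the data were seen. Grouping was by name alone, so a family can hold genes of another function. None passed with an estimated correlation, where camera adjusted p was at least 0.76, so the values below rest on the preset one. The CDKN group, named after cyclin-dependent kinase inhibitors (6 of 8 lower, 1 higher, median log2 fold change -0.51), had the smallest camera adjusted p, 0.00023. The IRF group, named after interferon regulatory factors, fell (7 of 10 lower, none higher, median -0.40, camera adjusted p = 0.0025). So did the PSMB group, named after proteasome beta subunits (7 of 10 lower, 1 higher, median -0.17, camera adjusted p = 0.0075). The MT group, named after metallothioneins, rose (4 of 7 higher, none lower, median 0.89, camera adjusted p = 0.0020). So did the FKBP group, named after FK506-binding proteins (7 of 13 higher, none lower, median 0.20, camera adjusted p = 0.029). Scaling by library size in place of TMM moved the median of all genes from 0.0064 to 0.025.

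Many genes outside the Hedgehog lists changed by 2-fold or more, and 12 genes fell and 5 rose further than SMO fell. GC content and length held 0.0149 of the variance of log2 fold change, which argues against such a bias between libraries. The 7-mer CTACCGA in 3' UTRs went with lower levels (z = -16.41, against -5.31 to 5.40 in 100 permutations) and led in coding sequences too (z = -20.10). CTACCGA or TACCGAA, chosen on these same fold changes, was found in 56 of the 116 searched genes outside the Hedgehog lists that fell 2-fold or more. The share was 3.64% of such genes that rose 2-fold or more and 8.17% of all searched. These shares describe the reach of the pair and are no further test. CTACCGA occurs once in SMO mRNA, in the coding sequence, where 5.29% of genes searched carry it anywhere. Many falls may therefore be off-target silencing by an SMO siRNA, whose sequence, or sequences if it was a pool, are not given in the sources used here. Other 7-mers with the shared 6 bases TACCGA also lay below the permutations in 3' UTRs (TTACCGA z = -10.12, TACCGAG z = -9.76). Of the genes named here, FLG, NSDHL, SKI, SPARC, VLDLR, ANKRD1, MCM5, MBP and FBXW11, all lower, held TACCGA without CTACCGA or TACCGAA. GPR161, HIST1H2BD and GAD1, all higher, held it likewise.

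The rises of 2-fold or more are less accounted for. The 7-mer with the highest z in 3' UTRs, GGAGAAA (z = 7.36, 3030 genes), lay above the highest of 100 permutations (5.40) with a slope of 0.054, and TCGGAGA had a slope of 0.128 (z = 6.78) and CGGAGAA of 0.101. In coding sequences CGGAGAA led (z = 9.41, highest of the permutations 5.14). Release of genes held down by the control siRNA in siNC may therefore add to the rises. Coding 7-mers without the bases GGAGA also lay above the permutations, such as ATACTGG (z = 5.90) and AACCCTA (z = 5.83). The permutations treat genes of a family as independent. Zinc finger genes, which rose more often than they fell, were not left out of the scan. The coding z is therefore no separate sign of control siRNA matches. GGAGAAA, chosen on these same fold changes, was found in 26 of the 55 searched genes outside the Hedgehog lists that rose 2-fold or more. It was found in 24.6% of all searched, and these shares are no further test. A response to lower SMO stays open for the rises and for the falls without CTACCGA or TACCGAA, and these tests do not separate it from other effects of the siRNAs. Falls of genes with only TACCGA may also be off-target silencing.

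PTCH1 fell while GLI1 and HHIP did not pass the threshold. The PTCH1 mRNA held 0 matches to CTACCGA or TACCGAA in its 3' UTR and coding sequence, and 0 to their shared bases TACCGA. This argues against direct off-target silencing of PTCH1 through these sequences only. The siRNA sequences are not known, and matches to others, as in a pool, were not sought. The lower 95% limit of the GLI1 log2 fold change was -0.78, below the PTCH1 value of -0.67, so a GLI1 fall of that size may have been missed at this depth. For HHIP the limit was -0.13, so a fall like that of PTCH1 would have been seen. Lower Hedgehog signalling remains a hypothesis for the PTCH1 fall, with an indirect effect of other silenced genes untested.

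Of 472 zinc finger genes named ZNF, 164 rose and 37 fell (median 0.168; 174 and 31 by library size). The mean difference from other genes was 0.165 (SE 0.0155) after GC content, length and level were accounted for, which argues against these as the cause. The control siRNA is a candidate source, and the choices of 7-mers and genes gave different answers. With CGGAGAA and TCGGAGA in 476 genes of the wider family, those with none had a median of 0.149 (95% bootstrap interval 0.080 to 0.183; other genes with none, -0.020), while with GGAGAAA added, in 436 ZNF genes, those with none had 0.0267 (-0.026 to 0.106; other genes with none, -0.040). This cannot be told apart from a biological rise, since the repeated linkers of zinc finger genes may themselves hold GGAGAAA.

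The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5999 genes and the highest other 0, and the real split gave 5 lists and the highest other 3. Each other split mixes siNC and siSMO samples, so the difference between the groups widens the spread within its sides. Few genes in these splits were therefore fixed in advance and say little about chance. The list counts do not test chance either, since a mixed split keeps part of the group difference. For example, siNC 1, siNC 2 and siSMO 2 against the others gave 3 lists with 0 genes changed. In each case 1 of the 10 splits, the real one, gave a result as large.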
